A study of Mus musculus with 4 samples.

How the data were processed

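RNA was measured by sequencing in 4 libraries of mouse embryonic fibroblasts (MEFs), primary connective-tissue cells grown out of C57BL/6 embryos. MEFs carrying a floxed Mecp2 gene were compared with cells in which Mecp2 had been deleted with Cre recombinase delivered on a plasmid, after which deleted clones were picked. Per the labels' protocols, total RNA was depleted of ribosomal RNA and made into strand-specific libraries. The groups were taken from the sample titles, which name WT replicates 1 and 2 and KO replicates 1 and 2. The genotype field gives the floxed genotype to replicate 1 and the deleted genotype to replicate 2 of both title groups, so it contradicts the titles. A cell fraction field names meiotic and post-meiotic cells, which are not fibroblasts, and was not used. The labels do not say that the 2 libraries of a group came from separate cultures or clones, so p-values measure only the spread between these libraries, which may be technical. Neither the deleted exons nor the number of clones is given in the sources used here.

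The submitters' processing notes name bcl2fastq 2.17.1.14, TopHat2 2.0.14 with Bowtie, HTSeq 0.6.1 and the mouse build mm9; the settings of each are not given in the sources used here. The strand setting of the counting and the release of the gene annotation are not given in the sources used here. Without the strand setting, genes that overlap another gene cannot be fully separated from it, and members of families of near-identical genes are uncertain in the same way. The deposited table holds raw read counts per gene for each library, per the file headers. It also holds a normalized signal, which the authors made by dividing the counts of each library by 1 constant (0.968 and 1.01 for WT, 0.771 and 1.35 for KO, as found from the ratio of both columns). The authors' deposited log2 ratio of KO to WT and their raw and adjusted p-values come from a test that the file headers do not name. That log2 ratio was moderated towards 0, since its median ratio to the plain log2 ratio of normalized means was 0.108 for genes with a mean normalized count under 10 and 0.992 for genes at 1000 or more.

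The table has 23417 genes with Ensembl identifiers, each with at least 1 count over the 4 libraries, and no row without a gene. A spreadsheet had turned 15 gene names into dates, and all 15 were restored from the identifier. Chromosome, position, length and GC content came from GENCODE M21 (GRCm38), in which 21657 identifiers (92.5%) were found by identifier alone. Coordinates are those of GRCm38 from this annotation and no position was converted from mm9. No genome sequence was used, so CA repeats in gene bodies were not analysed here and repeat runs were searched in spliced transcript sequences.

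Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with too few counts were removed with filterByExpr (minimum count 10), libraries were scaled by TMM, and the quasi-likelihood test (glmQLFit without the legacy fit, glmQLFTest) compared KO with WT in all 4 libraries without covariates. Standard errors (SE) were derived as the absolute log2 fold change over the square root of F. P-values were adjusted by the Benjamini-Hochberg method and genes under 0.05 were called changed; "rose" and "fell" are used of such genes alone. Levels are TMM-scaled CPM, the count divided by the scaled library total in units of 1e6, as mean ± SD of 2 libraries. A fold against a group at 0 counts is a lower bound set by 3 counts over the group, and a level of 1 to 3 counts is given as a ratio with its 95% exact interval. These limits cover counting error only.

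Before the data were examined, 42 gene lists were fixed: 29 of cellular programmes, 11 of other cell types and 2 of library quality. Lists with at least 5 tested members, and chromosomes, were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 and again with an estimated correlation. Members were counted over all genes and adjusted over the list alone. The genes to be named were also set by rule in advance. They are Mecp2, then the 12 largest rises and 12 largest falls by fold, and the 3 per direction with the largest change in mean CPM. All had to pass the test with a mean of at least 5 CPM and with both KO libraries beyond both WT libraries. Predicted or clone names of the Gm, Rik, AK, BC, LOC, Mir and Snor kinds were excluded. AC027184.1, a clone name of another kind, was kept. For each list described, up to 4 tested members with the smallest p are named. Where 5 or fewer members of a list passed in 1 direction they may be named too, and those outside the 4 were chosen after their values were seen.

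The test was checked on simulated counts for KO against WT, with 2 libraries per group and 15864 genes. It called 85% of 100 genes changed 1.3-fold, 98% of 100 genes changed 2-fold and 0.174% of 15528 unchanged genes. Camera called a list of 480 genes all shifted in the same direction and not an unchanged list of 480 genes. Genes were simulated as independent and few of them changed. Lists of correlated genes, and scaling where most genes change, were therefore not checked. Alternatives covered the scaling, the filter on low counts, the tool (DESeq2 1.42.0 and limma-voom), the replicate number as a block, the label that sets the groups, each library left out in turn, the correlation used for lists, and the length measure. Subtracting each chromosome's median, the crossed pairing and the search of transcripts for CA runs were chosen after the data had been seen.

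The libraries held 83106986 and 87815768 counts for WT and 64140845 and 110907790 for KO. Replicates differed by more than sampling noise, with a chi-square of 7.75 per degree of freedom over 13808 genes in WT and 8.08 over 14035 genes in KO, so none was counted as a duplicate. The common biological coefficient of variation was 3.80%.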

Results

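Gene expression was measured in 2 libraries of floxed control MEFs, titled WT, and 2 libraries of MEFs in which Mecp2 had been deleted, titled KO. MeCP2 is a chromatin protein that binds methylated DNA, and the series title names CA repeats as a sequence it binds. The comparison asks which transcripts differ between these groups. The KO cells were grown from picked clones, so loss of Mecp2 and clonal origin cannot be told apart in any difference below. The WT libraries held 83106986 and 87815768 counts and the KO libraries 64140845 and 110907790, so the shallowest and the deepest library were both KO. Between 20090 and 20935 genes had at least 1 count in a library. The most abundant transcript, the small nuclear RNA 7SK, took 1.88% to 2.40% of the counts. Pearson's r of log2 CPM across genes was 0.998 between the WT libraries, 0.998 between the KO libraries, and 0.932 to 0.933 between the groups, where genes are not independent replicates.

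Mecp2 (ENSMUSG00000031393; GRCm38 chromosome X, 74026592 to 74135363, minus strand, protein-coding) was lower in both libraries titled KO. Its level was 20.7 ± 0.64 CPM in WT and 10.3 ± 1.58 CPM in KO (SD, n = 2). The log2 fold change was -0.98 ± 0.08 (SE), with an edgeR adjusted p of 2.29e-10. The WT libraries held 21.2 and 20.3 CPM and the KO libraries 9.14 and 11.4 CPM, which left 49.5% of the WT level in KO. The authors' deposited table gives a log2 ratio of -0.99. The order of the libraries followed the titles and not the genotype field. The counts cover the whole gene, the deleted exons are not given in the sources used here, and 2 genes of the table overlap the Mecp2 span, 1 of them on the same strand.

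Among single genes, the smooth muscle actin gene Acta2 (6.02-fold) and the collagen gene Col3a1 rose in KO and the interferon-induced gene Ifit1 fell. Regulators of limb and body patterning went both ways. Tbx5, Lmx1b and Hoxb9 rose from trace level in WT, while Foxp2 fell from 66.4 to 2.52 CPM and Hoxd12 from 5.93 to 0.200 CPM, and neither of the fixed lists that hold them passed its test. In all, 9346 of 16208 tested genes (57.7%) changed, of which 4442 rose and 4904 fell (edgeR, adjusted p under 0.05). Upper quartile scaling turned this balance, with 5349 up and 4179 down. Most changes were small, with a median absolute log2 fold change of 0.45 among changed genes, and 2550 of them changed by less than 1.2-fold. At least 2-fold changes were found in 2230 genes (1173 up, 1057 down) and at least 8-fold changes in 598 genes (274 up, 324 down). In 12299 genes (75.9%) both KO libraries lay on the same side of both WT libraries, where chance gives 33.3%. The authors' deposited table has 7816 genes under an adjusted p of 0.05. Of these, 7808 were tested here, and all 7808 were called in the same direction. Both sets of calls rest on the same 4 libraries, so this is not independent evidence.

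Among the 12 largest rises at a mean of at least 5 CPM were genes nearly silent in WT. Angpt1, which encodes the TIE2 ligand angiopoietin 1 (chromosome 15, 42424723 to 42676977, minus strand), rose from 0.143 ± 0.0049 to 32.6 ± 0.32 CPM, a log2 fold change of 7.81 ± 0.15. Postn, encoding the matrix protein periostin (chromosome 3, 54361109 to 54391037, plus strand), rose from 0.764 ± 0.041 to 109.6 ± 0.70 CPM (log2 7.16 ± 0.08). The insulin-like growth factor binding protein gene Igfbp2 rose from 0.577 ± 0.21 to 74.9 ± 2.16 CPM (7.03 ± 0.10). Genes for 3 developmental transcription factors were in this set. Lmx1b, a regulator of dorsal limb identity, rose by 7.20 ± 0.15 on the log2 scale to 26.6 ± 0.24 CPM. Tbx5, a regulator of forelimb and heart formation, rose by 7.09 ± 0.19 to 19.07 ± 1.75 CPM. Osr1, expressed in embryonic connective tissue, rose by 6.61 ± 0.12 to 34.5 ± 1.07 CPM. Cxadr, the coxsackievirus and adenovirus receptor on chromosome 16, rose from 6.08 ± 0.35 to 320.0 ± 4.92 CPM (5.72 ± 0.05). The other rises were in Arsj (7.28), Cxcl15 (5.62), Adam12 (5.16), Kalrn (5.12) and Ankrd1 (5.06). The edgeR adjusted p of all 12 was at most 1.71e-16. Arsj, Cxadr and Adam12 overlap other genes of the table.

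At a mean of at least 5 CPM, the 12 largest falls were in genes between 10.4 and 226.0 CPM in WT and at or under 0.487 CPM in KO. That minimum sets the lower end of the WT range. Pcdh7, a protocadherin (chromosome 5, 57717967 to 58133230, plus strand), fell from 226.0 ± 2.41 to 0.487 ± 0.15 CPM, a log2 fold change of -8.78 ± 0.08. Efemp1, encoding the matrix protein fibulin-3 (chromosome 11, 28853204 to 28926743, plus strand), fell from 89.8 ± 0.18 to 0.233 ± 0.069 CPM (-8.50 ± 0.10). Prg4, encoding the joint lubricant lubricin, fell from 52.99 ± 3.78 to 0.273 ± 0.061 CPM (-7.53 ± 0.12). The guanine deaminase gene Gda fell from 51.3 ± 0.16 to 0.260 ± 0.044 CPM (-7.66 ± 0.12). The others were the adhesion gene Sdk1 (-7.56), the axon guidance receptor gene Robo2 (-7.06), the progenitor marker Cd34 (-6.90), Tchh (-8.70), the prostaglandin receptor gene Ptger3 (-8.36), Samd5 (-7.65), Syt7 (-7.30) and Raet1d (-6.91). The edgeR adjusted p of all 12 was at most 1.49e-17. Sdk1, Prg4, Robo2 and Raet1d overlap other genes of the table, and Raet1d has close paralogs.

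**Figure D1:**
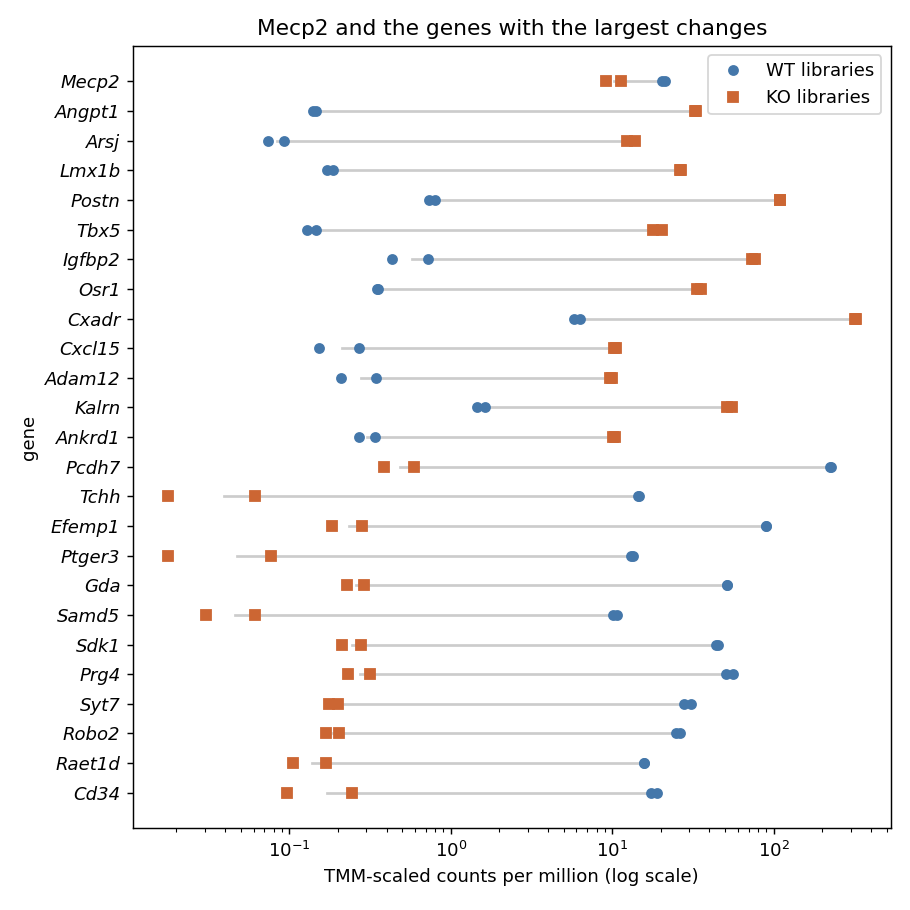
TMM-scaled CPM (horizontal, log scale) of Mecp2, the 12 genes with the largest rise and the 12 with the largest fall (vertical), with circles for the 2 WT and squares for the 2 KO libraries and a grey line joining the group means. Replicates lie close together beside the distance between groups, as for Pcdh7 at 226.0 CPM in WT and 0.487 CPM in KO. Apart from Mecp2, the genes were picked for large changes without overlap between the groups, which favours this picture.

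By change in CPM, the largest falls were in the ribozyme RNA gene AC027184.1 (log2 -0.44 ± 0.04), which overlaps Ccnb1ip1 on the same strand, in Ahnak (-0.46 ± 0.03) and in the nuclear long noncoding RNA Malat1 (-0.47 ± 0.03). The smooth muscle actin gene Acta2 rose from 276.4 ± 2.03 to 1663 ± 10.7 CPM (2.59 ± 0.03) and the collagen gene Col5a2 from 1728 ± 2.98 to 3246 ± 90.2 CPM (0.91 ± 0.03). 7SK rose by 0.16 ± 0.04 (edgeR adjusted p = 0.00152). That call was lost without WT replicate 1 (adjusted p = 0.116), without KO replicate 1 (adjusted p = 0.258) and with DESeq2 (adjusted p = 0.235), in a range of 8.55e-11 to 0.258 over the alternatives. Acta2, Ahnak and Malat1 lie on chromosome 19, whose genes were lower as a group at the preset correlation (camera adjusted p = 2.51e-06) but did not pass with an estimated one (adjusted p = 0.206).

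**Figure D2:**
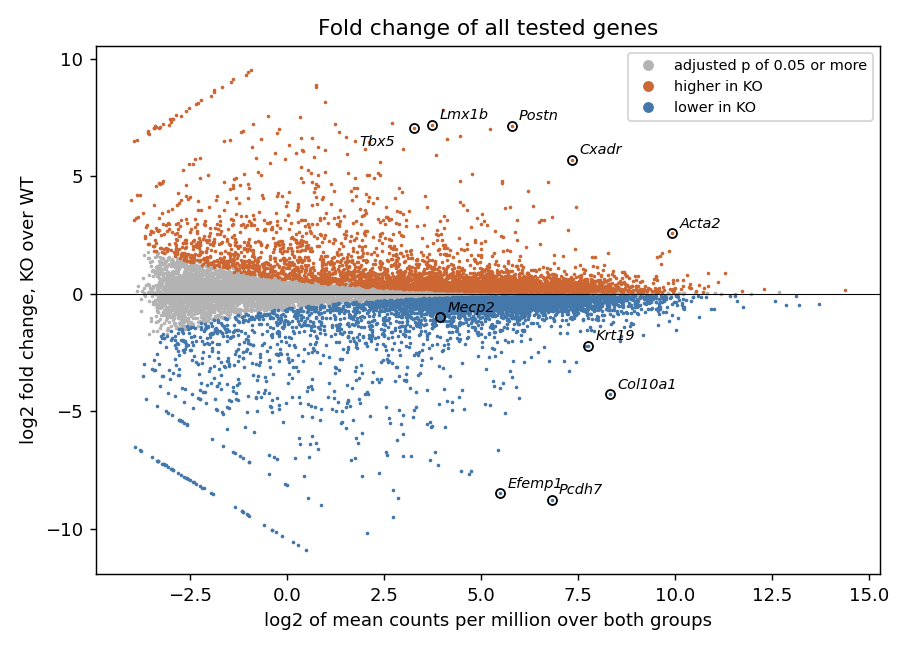
Log2 fold change of KO over WT (vertical) against the log2 of mean CPM over both groups (horizontal), with 1 point per tested gene and coloured points for genes under an edgeR adjusted p of 0.05. The 4442 genes that rose and the 4904 that fell span the range of expression, and the diagonal streaks at low level are genes with 0 counts in 1 group, whose fold depends on the prior count.

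Of the 40 fixed gene lists with enough tested members, 10 passed camera at the preset correlation, 5 higher and 5 lower in KO. None of the 10 passed with an estimated correlation, which gave adjusted p from 0.481 to 0.781, and 2 of the 40 lists had an unadjusted p under 0.05 there. That test rests on the few residual degrees of freedom of 2 libraries per group, where small p-values can hardly be reached. A miss there decides little, and the calls stay dependent on the preset value. The counts of members adjusted over the list alone equalled those over all genes in each called list except that of amino acid and unfolded protein stress. All 10 list medians were the same with genes at 0 counts set to their bound.

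Contractile genes, targets of the transcription factor SRF, were higher in KO. Of 23 tested members 18 rose, and the integrin gene Itga7 (log2 -0.20) was the 1 that fell (median 0.39, camera adjusted p = 1.19e-14; adjusted p = 0.48 with an estimated correlation). The myosin light chain gene Myl9 rose from 24.9 ± 0.47 to 320.9 ± 6.85 CPM (3.69 ± 0.04), Tagln, the gene for transgelin, rose by 1.75 and Lmod1, a leiomodin of smooth muscle, by 4.16. Collagens and other matrix genes were higher too, with 21 of 34 members up and 10 down (median 0.29, camera adjusted p = 4.85e-12; adjusted p = 0.54 with an estimated correlation). Besides Postn, the collagen gene Col3a1 rose by 3.16, the laminin gene Lamb1 by 2.71 and the collagen cross-linking enzyme gene Lox by 1.82 on the log2 scale.

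Interferon-stimulated genes were lower in KO. Of 39 members 29 fell, 16 of them at least 2-fold, and Tap1 (0.94) and Irgm1 (0.25) rose (median -0.80, camera adjusted p = 2.28e-04; adjusted p = 0.54 with an estimated correlation). The RNA sensor gene Ifih1 (-1.94), Ifit2 (-0.99), Ifit1 (-3.48) and the MHC class I light chain gene B2m (-0.72) were among them. In the list of NRF2 targets and metallothioneins, 16 of 25 members fell and Aldh3a1 (2.68), Osgin1 (0.35) and Gclc (0.11) rose (median -0.18, camera adjusted p = 0.00508; adjusted p = 0.54 with an estimated correlation). The quinone reductase gene Nqo1 fell from 15.6 to 0.217 CPM (-5.98 ± 0.18), as did the metallothionein genes Mt1 (-1.29) and Mt2 (-1.32) and the thioredoxin reductase gene Txnrd1 (-0.63).

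Histone and mitotic genes were lower at the preset correlation, and genes of S phase were not called. Of 47 replication-dependent histone genes 32 fell and Hist1h2bc (0.19) rose (median -0.22, camera adjusted p = 0.00216; adjusted p = 0.78 with an estimated correlation), among them Hist1h1a (-1.42), Hist1h3a (-1.37), Hist1h4a (-0.72) and Hist1h4h (-0.52). These genes are near-identical copies, so single members are uncertain. Of 30 mitotic genes 21 fell (median -0.29, camera adjusted p = 0.0182; adjusted p = 0.78 with an estimated correlation), such as Nusap1 (-0.79), Birc5 (-0.64), Ccnb2 (-0.62) and Top2a (-0.47), while Cenpe, Tpx2, Aurka, Cdk1 and Kif23 rose by 0.11 to 0.30. Of 31 genes of S phase 18 fell and 6 rose, with a camera adjusted p of 0.409. Pcna (-0.67), Mcm10 (-0.65) and Rrm2 (-0.52) fell and Ccne1 (0.91) rose.

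The list of p53 targets and senescence genes was higher, with 18 of 27 members up (median 0.32, camera adjusted p = 0.00108; adjusted p = 0.54 with an estimated correlation). The apoptosis effector gene Perp rose by 2.11, the kinase gene Plk2 by 1.08 and the receptor gene Eda2r by 1.90. The 5 that fell were Glb1 (-0.91), whose product is the senescence-associated beta-galactosidase, Cdkn2b (-0.38), Cdkn1b (-0.28), Pmaip1 (-0.24) and Trp53 itself (-0.12). Of 24 genes of cholesterol synthesis 19 rose and Ebp (-0.38) fell (median 0.33, camera adjusted p = 0.00138; adjusted p = 0.54 with an estimated correlation). The sterol enzyme genes Dhcr24 (0.88), Hsd17b7 (0.85), Sc4mol (0.65) and Cyp51 (0.61) led this list, and no member changed 2-fold. Of 29 genes of amino acid and unfolded protein stress, the ATF4 list, 17 rose and 6 fell, or 7 adjusted over the list alone (median 0.24, camera adjusted p = 0.0391; adjusted p = 0.62 with an estimated correlation). The serine synthesis genes Psph (0.89) and Phgdh (0.60) and Shmt2 (0.64), whose enzyme converts serine to glycine, rose and the lipoprotein receptor gene Vldlr fell by 0.98.

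Markers of epithelium and keratinocytes, fixed as a check for other cells, moved with the groups. Of 12 tested members 7 fell and 4 rose (median -1.01, camera adjusted p = 0.0141; adjusted p = 0.54 with an estimated correlation). Keratin 19 (Krt19) fell from 355 to 76.5 CPM (-2.21 ± 0.04). Sfn (-2.93) and the plakophilin gene Pkp1 (-1.24) fell, while Perp rose as above. Trp63 (1.58), Cdh1 (0.92) and Krt8 also rose, with means of 1.85 CPM or less in both groups. Krt8 had no count in WT and was at least 12.1-fold higher in KO.

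**Figure D3:**
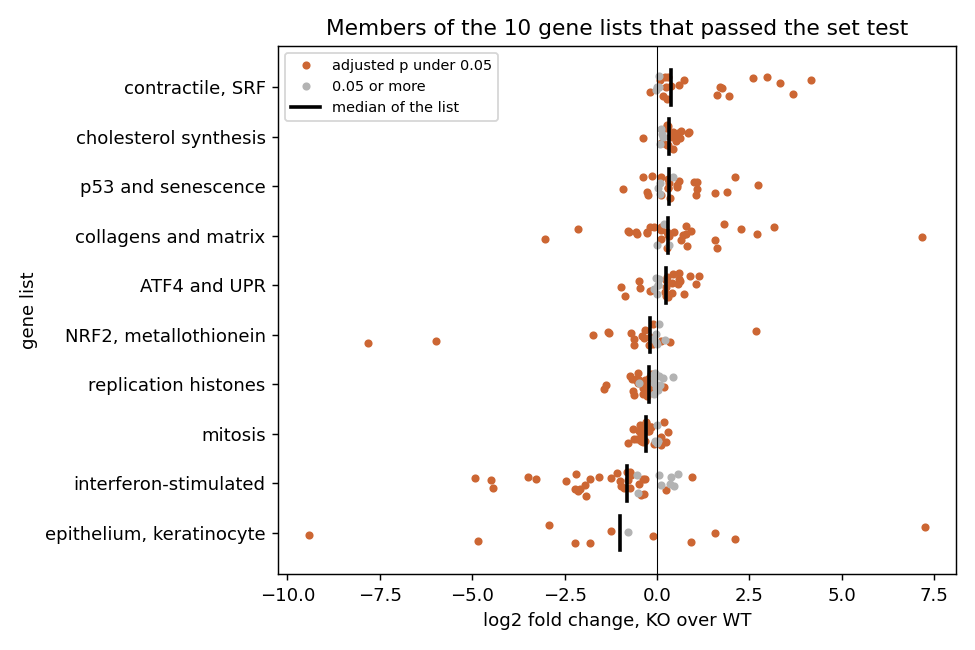
Log2 fold change of KO over WT (horizontal) for the tested members of the 10 gene lists (vertical) that passed camera at the preset correlation, with orange points for genes under an edgeR adjusted p of 0.05, grey points for the rest and a bar at each list median. Medians run from -1.01 for epithelial genes to 0.39 for contractile genes, and points beyond 7 include genes with 0 counts in 1 group.

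The remaining 30 tested lists did not pass (camera adjusted p from 0.0628 to 0.966). Many of their members changed in both directions, as did 57.7% of all tested genes (27.4% up, 30.3% down). Counts of members near these shares do not set a list apart. Of 23 partners of MeCP2 and other methyl-DNA binding proteins, 6 rose and 9 fell. Mecp2 is 1 of them, with the zinc finger gene Zbtb38 (-0.83), Mbd2 (-0.42) and the SKI family corepressor Skil (0.39). In the DNA methylation machinery 8 of 14 rose, with the de novo methyltransferase gene Dnmt3b at 1.79, Trim28 at 0.23 and Tdg at 0.28. Uhrf2 (-0.26), Tet3 (-0.25), Uhrf1 (-0.18), Hells (-0.14) and Idh2 (-0.13) fell. Of 17 genes described as MeCP2 targets in other tissues, Sgk1 (1.22), Opa1 (0.62), Id3 (0.33), Ube3a (0.19) and Fkbp5 (0.14) rose. Plagl1 (-2.84), Reln (-1.70), Prodh (-1.19), Bdnf (-0.88) and Id2 (-0.61) fell. Among chromatin remodellers and histone variants 14 of 37 rose and 13 fell, led by Chd3 (-1.10), H2afy2 (1.39), Hmgn1 (0.74) and Hmgn2 (0.93).

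Among YAP targets 8 of 14 rose and 6 fell, with rises in Crim1 (1.16), Ctgf (0.90), Ankrd1 and Nuak2 (0.66). The list missed the threshold (camera adjusted p = 0.0628) and passed without WT replicate 1 (adjusted p = 0.0494), without KO replicate 1 (0.0386) and with no filter on low counts (0.026), in a range of 0.026 to 0.741 over the camera alternatives. Of 19 hedgehog and Notch genes 9 rose, Gli3 (-0.89) fell and 9 did not pass. The rises included Boc (1.42), Hhip (4.12, from 0.186 to 3.18 CPM) and Gli2 (3.22, from 0.355 to 3.28 CPM). This list had a camera adjusted p of 0.0765, or 0.0386 without KO replicate 1 and 0.0363 with no filter on low counts, in a range of 0.0299 to 0.741 over the camera alternatives. In the TGF-beta and BMP list 10 of 32 rose and 14 fell, led by Ltbp2 (-2.65), Fstl1 (0.89), Tgfb2 (-1.27) and Smad9 (-1.14). In the Wnt list 10 of 33 rose, or 11 adjusted over the list alone, and 12 fell, led by Wnt10b (-1.71), Notum (-2.15), Wnt5a (3.02) and Dkk3 (-4.65). Its median (0.11) and mean were above 0 and its test pointed down. Of 33 growth factors and receptors 12 rose and 13 fell, or 14 adjusted over the list alone. Besides Igfbp2, Pdgfrb (1.13), Vegfa (1.05) and Fgf7, from 36.5 to 84.0 CPM, rose, and the list had a median below 0 with a mean and a test above it.

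Inflammatory genes (9 up, 8 down of 25) included rises in Cxcl12 (1.90), Tnfaip3 (1.24) and Ptgs2 (0.84) and a fall in Il1rl1 (-0.97), with the mean below 0 and the median and test above it. That mean includes a member at 1.52 CPM in WT with no count in KO, whose fitted log2 of -10.04 depends on the prior count. Immediate early genes (8 up, 12 down of 24) included falls in Klf4 (-0.99), Jund (-0.99) and Klf6 (-0.49) and a rise in Myc (0.63), with the mean above 0 and the median and test below it. Hypoxia and glycolysis genes (15 up, 12 down of 30) included Pfkp (-2.02), P4ha1 (0.77) and Adm (1.45). Ribosomal protein genes (7 up, 19 down of 47) and oxidative phosphorylation genes (9 up, 16 down of 35) had medians of -0.04 and -0.06, and no member of either changed 2-fold. Of 12 mitochondrially encoded genes 7 rose, by 0.45 for mt-Nd3 and 0.24 for mt-Nd1, and mitochondrial genes took 1.12% and 1.13% of WT counts and 1.29% and 1.26% of KO counts.

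Positional identity genes changed in both directions. Of 22 tested Hox genes 8 rose, or 9 adjusted over the list alone, and 9 fell (camera adjusted p = 0.966). Hoxb9 rose from 0.0714 to 6.68 CPM (6.53 ± 0.29) and Hoxb13 from 0.0297 to 4.72 CPM (7.24 ± 0.37), while Hoxd12 fell from 5.93 to 0.200 CPM (-4.80 ± 0.24) and Hoxd13 fell too (-0.52). The list's median (0.22) and mean were above 0 and its test pointed down. Of 36 transcription factors of mesenchymal patterning 15 rose and 13 fell (camera adjusted p = 0.248). With Osr1 and Lmx1b up, Foxp2 fell from 66.4 to 2.52 CPM (-4.68 ± 0.08) and Prrx1 from 390 to 149 CPM (-1.38 ± 0.03).

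Fold changes differed by chromosome. Genes of chromosome 16 were higher as a group, with a median log2 fold change of 0.50 (1.41-fold), 347 of 482 genes up and 38 down (camera adjusted p = 1.07e-17; adjusted p = 0.125 with an estimated correlation). Genes of chromosome 19 were lower, with a median of -0.34 and 302 of 493 genes down and 46 up (camera adjusted p = 2.51e-06; adjusted p = 0.206 with an estimated correlation). Chromosomes 6 (median -0.25, adjusted p = 0.00131) and 11 (-0.19, 0.0075) were lower, and 12 (0.21, 0.0075) and 1 (0.15, 0.0347) were higher (adjusted p from 0.169 to 0.206 for these 4 with an estimated correlation). Among the 20 chromosomes tested these 6 passed at the preset correlation, and none passed with an estimated correlation, where 3 had an unadjusted p under 0.05. As for the lists, small p-values can hardly be reached in that test with 2 libraries per group. The call of chromosome 1 was lost without WT replicate 2 (adjusted p = 0.0501), without KO replicate 1 (0.053) and with no filter on low counts (0.0968), in a range of 9.88e-04 to 0.206 over the alternatives. With the genes of a chromosome divided by position into 4 segments of like gene number, the medians on chromosome 16 were 0.48, 0.56, 0.47 and 0.47, and those on chromosome 19 were -0.40, -0.38, -0.35 and -0.24. Chromosome 2, which was not called, had segments that went apart, at -0.05, -0.31, -0.26 and 0.24. Between the 2 libraries of a group the median of a chromosome moved by between -0.0186 and 0.0154.

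**Figure D4:**
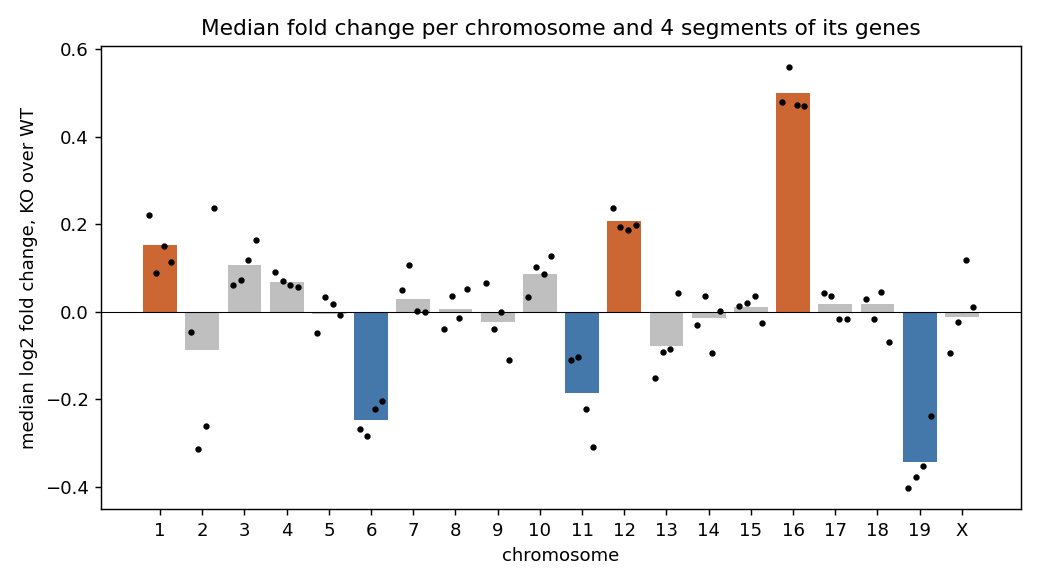
Median log2 fold change of KO over WT (vertical) for the tested genes of each chromosome (horizontal), with coloured bars for the 6 chromosomes that passed camera at the preset correlation and black points for 4 segments of a chromosome's genes in order of position. All 4 segments of chromosome 16 lie at 0.47 or above and all 4 of chromosome 19 at -0.24 or below.

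A relation of gene length to loss of MeCP2 is an open question in the field. The tests here covered a shift in 1 direction, where rises and falls cancel. Whether long genes changed more often in either direction was not tested. Of 1874 tested genes longer than 100 kb, 615 rose and 720 fell, where 27.4% of all tested genes rose and 30.3% fell. Their median log2 fold change was -0.036 beside 0.0045 for the other annotated genes. The difference of -0.040 did not pass limma's camera (adjusted p = 0.707 over the tests of length and CA runs; adjusted p = 0.87 with an estimated correlation). Spearman's rho of gene length and fold change was -0.027 across genes, which are not independent replicates. It turned to 0.0057 with a filter at 1 CPM and was -0.043 without WT replicate 2 and -0.013 without KO replicate 1. With exonic length in place of gene span the difference turned to 0.026 and did not pass either. Of the 1874 genes longest in exonic length, 676 rose and 650 fell. CA runs of at least 20 units were found in the spliced transcripts of 854 of 15347 searched genes, of which 270 rose and 259 fell. Their median was 0.03 beside -0.002 for the other genes, and limma's camera gave an adjusted p of 0.707 over the same 2 tests (adjusted p = 0.87 with an estimated correlation). Among 10000 random lists of matched exonic length that median lay at the 96.7th percentile. With minimums of 10, 15 and 30 units (2072, 1462 and 44 genes) the medians of 0.031, 0.037 and 0.114 lay at percentiles 99.9, 99.9 and 94.2. Camera gave unadjusted p of 0.86, 0.825 and 0.669 for these 3 sets. The random lists drew genes as independent and were matched on exonic length alone, so their percentiles do not show an effect of CA runs.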

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

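Centring each chromosome and the crossed pairing were chosen after the data had been seen. Of 420 values for the 30 named genes besides Mecp2 under alternatives that kept the titled groups, 416 kept their direction and side of the threshold and the 4 others, all of 7SK, lost the call. Most of these genes were picked from the same data for the largest changes, so this stability follows from the choice and does not extend to other genes. With the groups set by the genotype field, Mecp2 turned to 0.058 and edgeR called 0 genes (42 at an unadjusted p under 0.05). With the remaining split Mecp2 was at -0.14 and edgeR called 0 genes (73 unadjusted). Both mix titled groups, which shows the cause. A 2-fold minimum left 2230 genes by construction. Other scalings, filters and tools gave 8034 (DESeq2) to 9528 (upper quartile) changed genes. After centring, 8881 genes were called, 7955 of them shared with the same direction, and the TGF-beta and cartilage lists joined the 10 (adjusted p = 0.045 for both). An estimated correlation called 0 lists and 0 chromosomes, with 2 and 3 at an unadjusted p under 0.05, and fry, which does not compare a list with other genes, called 31 lists. With 2 libraries per group the estimated correlation rests on few residual degrees of freedom, so small p-values can hardly be reached. For centring, scaling, filter, tool and fry the cause was not tested.

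Leaving out 1 library gave 8245 to 9018 changed genes, Mecp2 between -1.18 and -0.86, 10 to 12 lists, 5 to 6 chromosomes and a gene length difference of -0.059 to -0.020. The library left alone in its group is then assumed to vary like the others. Exonic length reversed the length difference to 0.026, and the cause was not tested. The deviations of WT replicate 1 and KO replicate 1 correlated at -0.186 across genes, so the numbers do not pair the samples. With the replicate block 9075 genes and 10 lists were called. It ended the calls of the epithelial list (adjusted p = 0.0505) and 7SK (0.0748) and added the hedgehog and Notch list (0.0299). The crossed pairing called 9702 genes and 10 lists, 9 of them among the main 10. The CA repeat tests in gene bodies and at 5' ends were not run. Depth limits low genes, where a group at 0 counts gives only a lower bound.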

Other observations

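The tests on segments of chromosomes, clonal origin, epithelial cells and exon reads below were chosen after the results had been seen. Lists of lineage markers beyond those in the report held large changes of single genes, and camera called none of these lists in the comparison of all 4 libraries. Of 14 genes of cartilage and bone, 6 rose and 4 fell. The hypertrophic cartilage collagen gene Col10a1 fell from 612 to 31.6 CPM (log2 -4.28 ± 0.04), Sox6 from 120.02 to 5.53 CPM (-4.45 ± 0.06), and Matn3 (-1.85) and Col11a1 (-0.39) fell too, while Spp1 (osteopontin) rose from 71.9 to 269.9 CPM. This list had a camera adjusted p of 0.0693, or 0.0494 without WT replicate 1, 0.0173 without WT replicate 2 and 0.045 with chromosomes centred, in a range of 0.0173 to 0.882 over the camera alternatives, with a median above 0 and a test pointing down. Among 24 matrix proteases and inhibitors 10 rose and 11 fell, with the gelatinase gene Mmp2 down from 37.2 to 1.18 CPM, the cathepsin gene Ctsk down from 33.2 to 0.651 CPM, and with Serpine2 at -2.48 and Adamts1 at 1.56 on the log2 scale. Its test pointed down with a median above 0. Of 22 imprinted genes 10 fell, including Plagl1 (-2.84), Ppp1r9a (-5.29) and Cd81 (-0.67). H19 (2.70), Mest (1.38), Cdkn1c (2.73), Igf2 (1.92) and Gnas (0.11) rose, with Igf2 at 0.191 CPM in KO. In the adipocyte list 5 of 10 rose and 4 fell, with Pparg at -2.27, Agpat2 at -1.01, Cebpa at 5.20 and Plin2 at 1.00.

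Neural genes were split (4 up, 4 down of 9), with the median above 0 and the mean and test below it. Stmn2 fell from 36.9 to 1.45 CPM, Nrcam fell from 10.4 to 1.52 CPM, Ncam1 rose from 7.10 to 56.4 CPM, and Sox2 had 2 counts in KO against 1.67 CPM in WT, a ratio of 150.1 (exact 95% interval 41.2 to 1245). Of 5 pluripotency genes Klf4 (-0.99), Tbx3 (-2.96) and Sox2 fell. Of 11 skeletal muscle genes 6 rose and Tnni2 (-1.25) fell. Of 7 Schwann cell and melanocyte genes Plp1 (0.95) and S100b (1.46) rose and Mitf (-1.19) and Erbb3 (-1.47) fell, with the median above 0 and the mean and test below it. Of 9 endothelial genes Flt1 (1.43), Tek (0.49) and Egfl7 (0.40) rose and Plvap (-1.47) and Tie1 (-1.12) fell, with the test pointing up and the median and mean below 0. Of 6 pericyte genes Mcam (1.41), Notch3 (2.97) and Des (1.95) rose and Cspg4 (-0.49) and Anpep (-2.06) fell. Of 5 blood cell genes Cd14 (2.02) rose and Mrc1, with 1 count in KO, fell (2 fell adjusted over the list alone), with the mean below 0 and the median and test above it. Of 7 germline genes Brdt (2.05) and Tdrd9 (2.62) rose and Stag3 (-1.01) fell. None of these lists passed camera. The mesothelial list had 4 tested members and no set test, with Krt19 and Msln (-1.25) down and Rspo1 (3.12) and Upk3b (0.84) up. The sex-linked list had 2, Xist (-0.03) and Uty (0.47), and neither passed.

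The shifts of chromosomes 16 and 19 did not follow GC content, exonic length or low counts. After a trend on GC content and exonic length was removed the medians were 0.503 ± 0.018 (bootstrap SE) and -0.33 ± 0.018, and among genes of at least 50 CPM they were 0.50 and -0.386. All 4 segments by position of both chromosomes moved beyond 50% of the chromosome's median, which a difference in copy number of the whole chromosome between the cells needs. The same held for chromosomes 1, 6, 11 and 12 and for 3 and 4, which were not called, so it does not single out 16 and 19. On the log2 scale a step from 2 to 3 copies is 0.58, from 3 to 4 is 0.42, from 4 to 5 is 0.32 and from 4 to 3 is -0.42. A difference in copy number, arisen in all or part of either the KO or the WT cells, is a candidate explanation for both. DNA was not measured, and a regulatory effect spread over a chromosome stays open.

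The 598 genes changed at least 8-fold, which include Lmx1b, Tbx5, Osr1, Hoxb9 and Pcdh7, were not gathered on the shifted chromosomes. On the 14 chromosomes that were not called there were 405 of 10904 tested genes (3.71%), and on the 6 called ones 175 of 4416 (3.96%; Fisher's exact test, two-sided p = 0.483). The other 18 of the 598 have no position in the annotation and were left out, among 888 tested genes without a position or on Y or the mitochondrial genome. A copy step of at most 0.58 is too small to change a gene 8-fold directly, so this count could not test copy number as the cause, and indirect effects of copy number stay open. Epcam, Cdh1, Krt8, Krt18 and Krt5 reached at most 0.60 CPM in WT beside Krt19 at 355 CPM. This argues against epithelial cells with these markers in the WT cultures as the source of the epithelial list's fall. The other members of the list were not part of this check, so cells without these markers stay open. KO cells were grown from picked clones, and expression inherited from the founder cell may account for part of the 598 genes. Clonal origin and loss of Mecp2 cannot be told apart, because the labels tie the KO libraries to no number of clones.

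Mecp2 RNA stayed at 49.5% of its WT level in KO (44.1% and 54.9% in the 2 libraries). Cells like those of the WT libraries, mixed into the KO cultures, would carry other WT transcripts at a like share. However, 62 of 8969 genes with at least 10 CPM in WT lay under 10% of that level in both KO libraries, with a median of 3.11%. This check could not detect cells with intact Mecp2 that otherwise express like the KO cells. Reads from Mecp2 exons outside the deleted part may make up the remaining 49.5%, and this cannot be told apart from lower transcription of the whole gene because the table counts genes and not exons.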
